A study of Mus musculus with 12 samples.

How the data were processed

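RNA from the renal medulla of 3 water-restricted mice and 3 control mice was amplified and hybridised to 2-colour arrays, per the labels. Each water-restricted mouse was set against each control mouse, which makes 9 pairs of mice. In 3 of these pairs (water-restricted mouse 1 with control mouse 3, 2 with 1, and 3 with 2) the arrays were made in both dye orientations, so the series holds 12 arrays. Channel 1 carried Alexa Fluor 546 and channel 2 Alexa Fluor 647, per the labels, and each orientation has 6 arrays.

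The authors deposited 1 log2 ratio of both channels per spot and array, for 31200 spots, with no missing value. The base was read from the values, which are signed, have array medians from -0.04 to 0.06, and reach -15.2, too large for a natural logarithm of a 16-bit signal ratio. The scanner signals, background correction, normalization and centring, and which dye is the numerator, are not given in the sources used here. No aligner applies, and signal over background could not be examined. The number of arrays limits the precision. Duplicate spots of a clone correlated at 0.362 to 0.684 within arrays, and the median residual SD between arrays was 0.40 on the log2 scale. Genes were taken from the platform annotation supplied with the values. Adjacent spots carried the same annotated clone, and the 2 spots were averaged, giving 15600 clones. Of these, 9191 had 1 gene, 254 had several and were not named, and 6155 had no gene in that annotation. The last group may include control spots, which could not be recognised. The symbols of 9085 clones were looked up through their Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, used for names only. Clones of a gene were averaged to 6786 genes.

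Values were turned to the orientation of arrays with the water-restricted mouse in Alexa Fluor 546, by changing the sign of the other 6 arrays. The rule, set before the data were examined, was to turn if dye-swapped pairs correlated below 0. Their correlations across clones were -0.14, 0.13 and -0.13 (mean -0.046), so the rule rests on a small value. Read as running by dye, 11.4% of clones had an unadjusted p under 0.05 for differences between mice, and read as already turned, 4.47% did. Which sign means higher in water restriction stays unknown.

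For each clone or gene, a weighted least-squares fit gave a level for each of the 6 mice, with arrays of a swapped pair weighing 0.5 each and a dye term. Levels were compared 3 mice against 3 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Array noise is shared by both groups, so this test is somewhat strict. Fixed gene lists, 32 in number, were written before the data were examined. Those with at least 3 measured genes, 29 of them, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry for change to 1 side. The mean level of each list was also compared by a two-sided permutation test over all splits of the mice, whose smallest p for 3 against 3 is 0.1. Every array compares a water-restricted with a control mouse, so array noise enters the real split and the others differently. The permutation p is therefore approximate. Differences between mice of the same group and the dye term were tested with limma on all 12 arrays, where the residual error is technical.

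Named genes followed a rule set before the data were examined. It took up to 10 genes per side past the threshold with 1 sign on all arrays, or else the 5 with the smallest p on that side. It also took all measured osmoprotective genes, up to 4 genes of each list that passed camera and of the vasopressin list, the 10 genes with the largest F between mice, and 3 clones with the smallest p of the dye term.

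The procedure was tested on simulated data. For the comparison of clones between groups, in a step of 15600 clones, it recovered 0 of 50 clones at a log2 size of 0.5, 31 of 50 at 1, 47 of 50 at 1.5 and 49 of 50 at 2, with 3 false calls among 130. For differences between mice it recovered 176 of 200 clones at a log2 size of 2, and for the dye term 194 of 200 at a size of 1. A proximal tubule list shifted by 1 gave a camera adjusted p of 4.69e-15 with the preset correlation and 0.0494 with an estimated one, and 1 other list was called. Noise was drawn independently for each clone, so genes of a list were simulated without correlation. This step therefore could not test the preset correlation. In the data, estimated correlations of the lists that passed camera ran from -0.03 (glycolysis and hypoxia) to 0.38 (ribosomal proteins), with 0.18 for proximal tubule.

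Alternatives set before the data were examined were median centring, scale normalization, the mouse number as a block, equal weights, no dye term, arrays of 1 orientation, arrays as replicates, swapped pairs alone, complete clones, robust eBayes, other thresholds, the median over clones, and leaving out each mouse. Alternatives added after seeing the data were leaving out the array of water-restricted mouse 2 against control mouse 2, random mouse effects, both together, annotated clones alone, and fry for change in either direction. Random mouse effects used 1 ratio of mouse to array variance for all clones (0.1) or genes (0.15). Fits on arrays of 1 orientation had no dye term, so a dye effect enters their differences between groups.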

Results

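The series asked how water restriction affects gene expression in the mouse renal medulla, the inner part of the kidney where urine is concentrated. Log2 ratios of 15600 clones were available on 12 arrays, which compare 3 water-restricted with 3 control mice in all 9 pairs. Array medians lay between -0.04 and 0.06. The SD over spots was 0.515 to 0.764 on 11 arrays and 1.21 on the array of water-restricted mouse 2 against control mouse 2.

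The side of the difference between groups has a sign but no settled direction. A positive value means higher in water-restricted mice if the deposited ratio is Alexa Fluor 546 over 647, and lower in them if it is the reverse. All values below share this 1 sign, so genes on opposite sides differ in opposite ways under either reading.

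Between water-restricted and control mice, Wnt4, a secreted signalling protein, and Hsd3b1, a steroid-synthesis enzyme, had the smallest p on their sides. The log2 difference of Wnt4 was -1.44 (SE 0.17, n = 3 mice per group, limma adjusted p = 0.183), and that of Hsd3b1 was 1.41 (SE 0.19, adjusted p = 0.239). Both had 1 sign on 12 of 12 arrays, and neither passed the threshold. Also on the positive side were Car4, a membrane carbonic anhydrase, at 1.31 (SE 0.22), Slc5a11, a sodium-coupled inositol transporter, at 1.02 (SE 0.18), Bche, or butyrylcholinesterase, at 0.94 (SE 0.15), and Arg2, the mitochondrial arginase, at 0.88 (SE 0.15). On the negative side with Wnt4 were Fxyd4, a regulator of the sodium pump in collecting duct, at -1.10 (SE 0.22), Slc40a1, the iron exporter ferroportin, at -0.96 (SE 0.18), Pdgfa, a growth factor, at -0.90 (SE 0.20), and Blnk, a B-cell adaptor protein, at -0.77 (SE 0.17). None of these 8 passed, with limma adjusted p from 0.386 to 0.553. Arrays of the same mice in both dye orientations could differ widely. Water-restricted mouse 3 with control mouse 2 gave 0.11 and 2.14 for Car4, and 1.78 and 0.29 for Bche. Mouse 2 with control mouse 1 gave 0.54 and 0.26 for Car4, and 1.85 and 0.09 for Bche. Mouse 1 with control mouse 3 gave 1.24 and 1.46 for Car4, and 1.02 and 0.77 for Bche.

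**Figure D1:**
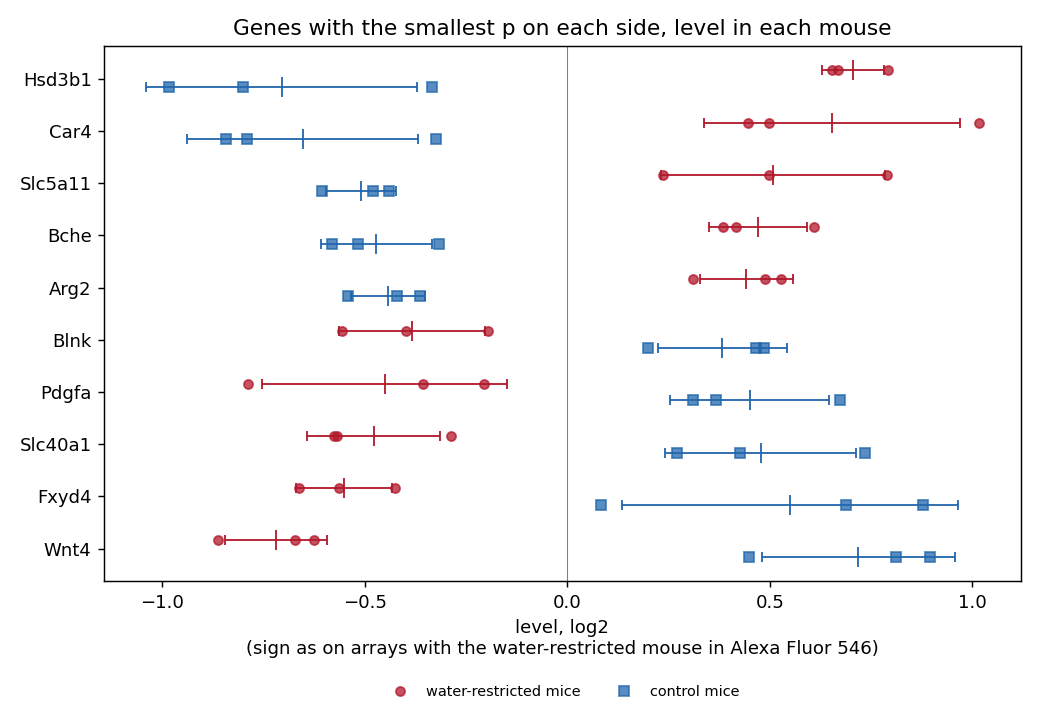
Level of the 10 genes with the smallest p on each side (x axis, log2, with the sign of arrays that carry the water-restricted mouse in Alexa Fluor 546). Points are mice, vertical ticks group means and bars 1 SD over 3 mice. The 3 water-restricted mice lie on 1 side of the 3 control mice for each gene, which follows from choosing genes by the p of this comparison. No gene passed the threshold.

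By limma, 0 of 15600 clones and 0 of 6786 genes passed the threshold, with smallest adjusted p of 0.586 and 0.183. At an unadjusted p under 0.05 there were 584 clones and 337 genes, 218 of the genes positive and 119 negative. The nominal rate would give 780 clones and 339.3 genes, but this test is stricter than its nominal rate. In simulation 2.04% of unchanged clones had an unadjusted p under 0.05, against 3.74% of the real clones. The real share of clones thus lay above the simulated one. A fit with random mouse effects, added after seeing the data, called 219 clones and 99 genes. Every gene named above was among them (limma adjusted p from 0.000189 to 0.0264). In simulation 24 of the 182 clone calls of this fit were false. That share depends on the changes planted and on noise drawn independently for each clone. It therefore does not give the share of false calls among the real clones or genes. On arrays with the water-restricted mouse in Alexa Fluor 647 alone, 1 gene passed, Hsd3b1 at 2.20 (SE 0.23, adjusted p = 0.0308), against 0.66 (SE 0.25, adjusted p = 0.887) on those with it in Alexa Fluor 546, and with the 3 swapped pairs alone 1 gene passed, Wnt4 at -1.43 (SE 0.13, adjusted p = 0.0363).

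Of 15 listed genes for the accumulation of organic osmolytes and for the response to hypertonicity, 5 were measured. Akr1b3, Slc5a3 and Slc6a12 were not among them. None of the 5 measured genes passed singly in the comparison of mouse levels. As a group they did not shift to 1 side by camera on all 12 arrays. By fry's test for change in either direction, added after seeing the data, the group passed (adjusted p = 0.00660). Of 5 measured osmoprotective genes 4 were positive. Sgk1, a kinase induced by corticosteroids and cell shrinkage, had 0.59 (SE 0.19), Hspa4l, a heat shock protein, 0.54 (SE 0.34), Slc38a2, an amino acid transporter, 0.41 (SE 0.24), and Slc6a6, the taurine transporter, 0.22 (SE 0.15). Nfat5, the transcription factor of the hypertonic response, had -0.84 (SE 0.34). The 3 clones of Slc6a6 disagreed, at -0.20, -0.09 and 0.94. Without the array of water-restricted mouse 2 against control mouse 2, Hspa4l had 0.30 and Slc6a6 0.09. The list's camera adjusted p was 0.119 and 0.484 with an estimated correlation. In the comparison of mouse levels 0 members passed over all genes or adjusted over the list alone. Under random mouse effects, a fit added after seeing the data, Sgk1 passed (limma adjusted p = 0.0458). The list passed camera on the positive side without water-restricted mouse 3 (adjusted p = 0.0488) and on arrays with the water-restricted mouse in Alexa Fluor 647 (0.0232), and with it in Alexa Fluor 546 the test pointed to the negative side (0.982) while the median was 0.10. In the list of water channels, urea transporters and vasopressin signalling, 6 of 20 genes were measured, and 4 of these 6 were negative. Aqp2, Aqp3, Aqp4 and Avpr2 were not measured. Avpr1a, a vasopressin receptor, had -0.49 (SE 0.15; -0.30 without the array of water-restricted mouse 2 against control mouse 2), Slc14a1, a urea transporter, -0.31 (SE 0.14), Adcy3, an adenylyl cyclase, -0.14 (SE 0.20), and Prkaca, a catalytic subunit of protein kinase A, -0.04 (SE 0.17). That list's camera adjusted p was 0.0925 and 0.484 with an estimated correlation.

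Markers of 2 nephron segments lay on opposite sides. Of 18 listed principal cell genes 5 were measured. All 5 were negative, with a median log2 difference of -0.59 and a camera adjusted p of 3.47e-06 (adjusted p = 0.268 with an estimated correlation). They included Fxyd4 at -1.10, the keratin Krt18 at -0.87 (SE 0.19), the transcription factor Gata3 at -0.59 (SE 0.18) and the matrix protein Npnt at -0.26 (SE 0.21). Of 31 listed proximal tubule genes 5 were measured. Among these 5, 4 were positive, with a list median of 1.05 and a camera adjusted p of 0.00149 (adjusted p = 0.356 with an estimated correlation). Gatm, which makes a creatine precursor, had 1.48 (SE 0.52), Miox, or inositol oxygenase, 1.43 (SE 0.32), the endocytic receptor Lrp2 1.05 (SE 0.35) and the organic anion transporter Slc22a7 0.67 (SE 0.52), while Cyp7b1 had -0.08. The permutation p of both list means was 0.1, the smallest possible. It was also 0.1 for the unfolded protein, respiratory chain, glycolysis and hypoxia, antioxidant, lipogenesis, vasopressin and erythroid lists, so it does not set these apart. For the chaperone and ribosomal lists the permutation p was 0.3. In the comparison of mouse levels, 3 principal cell and 3 proximal tubule genes passed when adjusted over the list alone, and 0 did over all genes. The proximal tubule median was 0.61 without control mouse 2, and on arrays with the water-restricted mouse in Alexa Fluor 546 the principal cell median was -0.38.

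The mean level of the proximal tubule list was 0.39, 0.43 and 0.54 in the water-restricted mice, 0.22 in control mouse 1, and -0.92 and -0.66 in control mice 2 and 3. Principal cell genes had -0.33, -0.28 and -0.33 in the water-restricted mice and 0.11, 0.32 and 0.51 in the control mice.

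**Figure D2:**
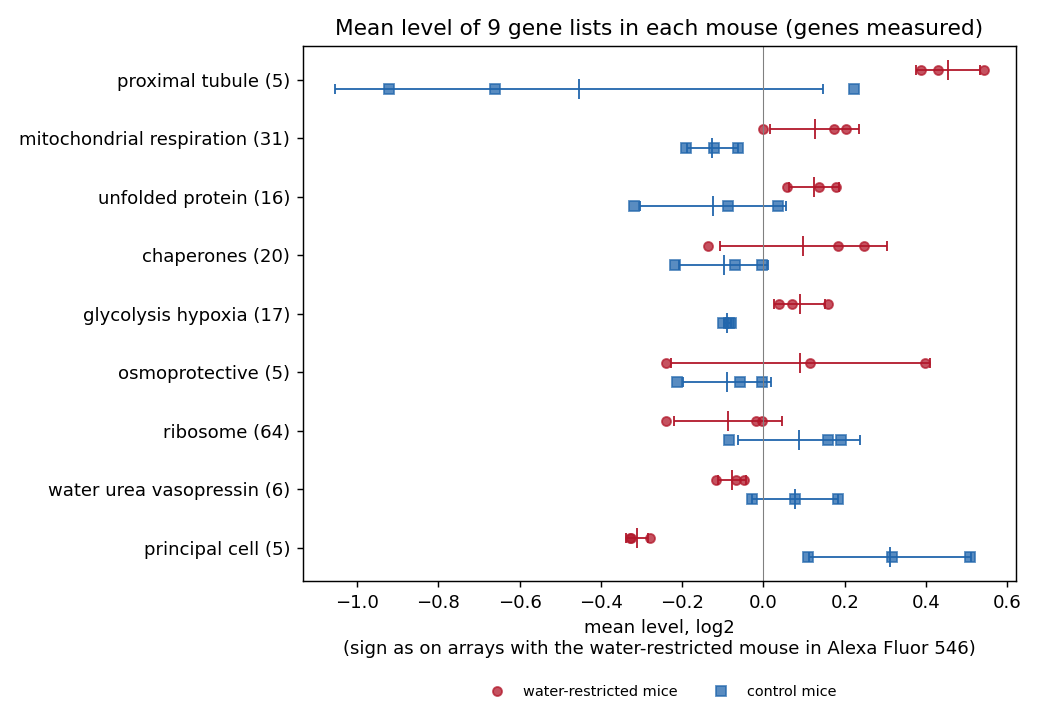
Mean level of 9 gene lists in each mouse (x axis, log2, with the sign of arrays that carry the water-restricted mouse in Alexa Fluor 546), with the number of genes measured. Points are mice, vertical ticks group means and bars 1 SD over 3 mice. Principal cell genes separate the groups, and for proximal tubule genes control mouse 1 lies at 0.22, nearest to the water-restricted mice.

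Protein folding genes lay mostly on the positive side. Of 16 genes of the unfolded protein response 13 were positive, with a median of 0.27 (camera adjusted p = 0.000982, and p = 0.356 with an estimated correlation). Among them were the transcription factor Atf4 at 0.77 (SE 0.24), the chaperone Hspa5 at 0.59 (SE 0.22), the secreted stress protein Manf at 0.55 (SE 0.17) and the co-chaperone Dnajc3 at 0.34 (SE 0.15). Single clones of Dnajc3 differed in size, at 0.23, 0.12 and 0.67. Of 20 chaperones 16 were positive, with a median of 0.27 (camera adjusted p = 0.00195, and p = 0.484 with an estimated correlation), including Hsph1 at 0.67 (SE 0.17), mitochondrial Hspd1 at 0.62 (SE 0.22) and Hspa9 at 0.43 (SE 0.19), and Bag3 at 0.35 (SE 0.19). The chaperone call was lost without water-restricted mouse 1 (adjusted p = 0.119), without water-restricted mouse 2 (0.0545), and on arrays with the water-restricted mouse in Alexa Fluor 647 (median 0.03, adjusted p = 0.612). The median was 0.17 without water-restricted mouse 1 and 0.15 without control mouse 2.

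Genes of energy metabolism lay mostly on the positive side and ribosomal protein genes on the negative side. Of 31 respiratory chain genes 30 were positive, with a median of 0.20 (camera adjusted p = 1.32e-07, and p = 0.451 with an estimated correlation), among them Cycs, or cytochrome c, at 0.48 (SE 0.15), Ndufv1 at 0.48 (SE 0.18), Ndufb9 at 0.46 (SE 0.16) and Uqcrc2 at 0.45 (SE 0.15). Of 17 genes of glycolysis and the hypoxia response 13 were positive, with a median of 0.10 (camera adjusted p = 0.0393, and p = 0.356 with an estimated correlation). The examples, Tpi1 at 0.51 (SE 0.18), Gapdh at 0.51 (SE 0.18), Aldoa at 0.48 (SE 0.21) and Pgk1 at 0.32 (SE 0.14), are all glycolytic enzymes. Of 64 ribosomal protein genes 57 were negative, with a median of -0.18 (camera adjusted p = 1.32e-07, and p = 0.484 with an estimated correlation), including Rpl21 at -0.42 (SE 0.16), Rps9 at -0.41 (SE 0.16), Rps26 at -0.34 (SE 0.16) and Rpl23 at -0.34 (SE 0.15). Ribosomal genes have near-identical copies that can share a clone's signal.

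These 3 lists depended on the dye orientation or on single mice. With the water-restricted mouse in Alexa Fluor 546 the ribosomal median was 0.04 (adjusted p = 0.982), and with it in Alexa Fluor 647 it was -0.44 (8.58e-15). In the latter arrays the respiratory median was 0.07 (adjusted p = 0.210) and the glycolysis median 0.10 (0.664), against 0.36 (7.36e-09) and 0.26 (0.00872) with it in Alexa Fluor 546. The ribosomal median was -0.08 without water-restricted mouse 1 and -0.10 without control mouse 2. The glycolysis call was lost without water-restricted mouse 1 (adjusted p = 0.119) or 3 (0.154) and without control mouse 1 (0.0964) or 3 (0.174), and its median was 0.05 without control mouse 1 and 0.17 without control mouse 2. Fry's directional test called 0 of the 29 lists, as did camera with an estimated correlation. Fry's test for change in either direction, which does not compare a list with other genes, called 3, the osmoprotective (adjusted p = 0.00660), principal cell (0.0195) and interstitium (0.0215) lists.

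Markers of other cell types did not pass camera on all 12 arrays. The adjusted p was 0.446 for intercalated cells, 0.579 for distal convoluted tubule, 0.916 for podocytes, 0.264 for endothelium, 0.304 for interstitium, 0.264 for leukocytes and 0.264 for urothelium. Erythroid transcripts (2 genes, median -0.62), thick ascending limb genes (2 genes, median 0.42) and adipocyte markers (1 gene, -0.38) were too few to test. Camera adjusted p was 0.0925 for cholesterol synthesis, 0.0925 for fatty acid oxidation, 0.119 for antioxidant genes, 0.264 for lipogenesis, 0.264 for kidney injury, 0.371 for prostaglandin synthesis, 0.423 for proliferation, 0.427 for interferon response, 0.452 for vasoactive hormones, 0.459 for p53 targets, 0.579 for the circadian clock, 0.916 for corticosteroid response and 0.966 for immediate early genes. Some of these lists passed camera in other fits at the preset correlation, among them the following. With an estimated correlation, used on all 12 arrays only, camera adjusted p was 0.458 for cholesterol synthesis and 0.524 for fatty acid oxidation. It was 0.484 for antioxidant genes, and 0.582 for urothelium and for kidney injury. Cholesterol synthesis passed without the array of water-restricted mouse 2 against control mouse 2 (adjusted p = 0.0203), with the swapped pairs alone (0.0129), with equal weights (0.0458) and without control mouse 1 (0.0431) or 2 (0.0469). Without control mouse 1 fatty acid oxidation (0.00982) and antioxidant genes (0.0122) also passed, as these 2 did with the water-restricted mouse in Alexa Fluor 546 (0.0143 and 0.0266), all on the positive side. On the negative side, urothelium passed with it in Alexa Fluor 647 (0.0280), and kidney injury without the array of water-restricted mouse 2 against control mouse 2 (0.0333). Adjusted over the list alone, 2 kidney injury genes and 1 erythroid gene passed. The kidney injury genes lay on opposite sides: Krt18, also a principal cell gene, at -0.87, and Cxcl1, at 1.53 under random mouse effects.

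Individual mice of the same group differed in 14 genes, 2 of them, Gatm and Slc22a7, among the 5 measured proximal tubule genes. Gatm had levels of 0.58, 0.49 and 1.15 in the water-restricted mice and of 0.65, -1.44 and -1.43 in control mice 1, 2 and 3 (F = 68.3, limma adjusted p = 0.000713). Slc22a7 had 0.91 in control mouse 1 and -1.23 and -0.68 in control mice 2 and 3 (adjusted p = 0.0218). The kidney membrane protein Tmem174 (0.62, -1.16 and -0.84), Acadm, an enzyme of fatty acid oxidation (0.51, -1.58 and -0.27), Calml4 (0.71, -1.22 and -0.46) and the steroid enzyme Hsd3b4 (-0.10, -1.75 and -0.72) likewise had their highest control level in mouse 1 and their lowest in mouse 2. Other genes stood apart in a single mouse. Control mouse 2 had 2.48 for the trafficking protein Rab6a, -2.17 for the coenzyme A hydrolase Nudt19 and 1.34 for the transcription factor Egr1, and control mouse 3 had 2.10 for Lbp, the lipopolysaccharide-binding protein.

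**Figure D3:**
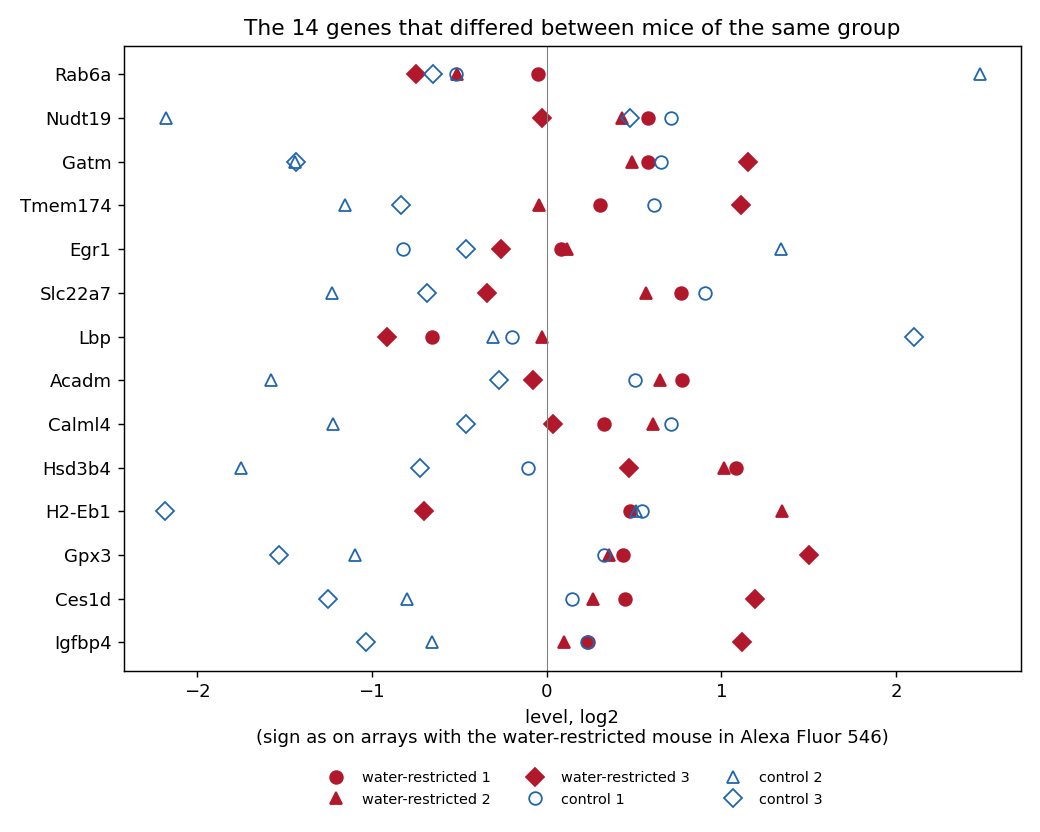
Level of the 14 genes that differed between mice of the same group (x axis, log2, with the sign of arrays that carry the water-restricted mouse in Alexa Fluor 546), with 1 symbol per mouse and no error bars. Rab6a, Nudt19 and Lbp each have 1 control mouse far from the other mice, at 2.48, -2.17 and 2.10.

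In all, 28 clones and 14 genes passed limma's F-test between mice of the same group, against the technical error between arrays. Without the array of water-restricted mouse 2 against control mouse 2, 175 clones passed, including those 28, and without the dye term 10 did. Without any 1 of the 6 mice 0 clones passed, in fits with fewer arrays, and without water-restricted mouse 2 there were 5 genes past the threshold, 4 of them among the 14.

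A dye effect, a dye term past the threshold, was found in 527 clones, 3.38% of all. The smallest p were those of clones of Pdxdc1 (5.43, SE 0.22, adjusted p = 2.35e-06), AI585793 (3.79, SE 0.33) and Jak1, a cytokine receptor kinase (2.00, SE 0.18). Among the genes named above, Hsd3b1 had a dye term of -0.77 and Krt18 of 0.52. With arrays of the swapped pairs alone 1 clone passed, and without the array of water-restricted mouse 2 against control mouse 2, 903 did. After turning, both arrays of a swapped pair correlated across clones, which are not independent replicates, at 0.14, -0.13 and 0.13, with a mean of 0.046 and of 0.178 after removal of the dye term. Arrays of the same dye orientation, none of which share both mice, had a higher mean of 0.197. The dye term was fitted to these same arrays. Its removal also raised r between opposite orientations with no mouse in common, for example from 0.04 to 0.31 for WR3 against C1 with WR2 against C2 (WR water-restricted, C control).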

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

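The tests on the widest array, on the error of the mouse test and on the side of the ratio were chosen after the results were seen. The tests on tissue share were written before their own results, but after the proximal tubule levels of the mice had been seen. For these, 2 details changed after a first result: the random lists were raised from 1000 to 10000, and the covariate difference was judged by its 95% interval in place of 2 SE. For the lack of calls, the widest array was at first taken as excluded by a count of 0 genes alone.

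Proximal tubule genes lay on the positive side and principal cell genes on the negative side. The array with the widest spread is argued against, since without it the medians were 0.88 and -0.59 and both lists passed camera at the preset correlation (on all arrays neither passed with an estimated one, at 0.356 and 0.268). A different share of proximal tubule tissue in the dissected pieces stays open: across 6776 other genes, the slope on the proximal tubule level within groups correlated with the difference between groups at r = 0.354, the percentile 94.33 among 10000 random lists of 5 genes, where the bound was 95 (95.1 among the first 1000 lists, 96.27 without the widest array), so it lies near the bound and crosses it with 1 array. As the whole cause of the principal cell shift it also stays open: the difference of -0.62 (SE 0.12) became -0.40 (SE 0.15) with the proximal tubule level as a covariate, 2.71 SE from 0, which met the bound of 2 SE written beforehand for excluding it, but that bound was too loose for 3 residual degrees of freedom, where the 95% interval runs from -0.87 to 0.07. An effect of water restriction on these genes stays open too, and the explanations cannot be told apart with 3 mice per group.

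No gene passed, while 139 genes had 1 sign on all 12 arrays (0.0488% of genes would by chance if arrays were independent, which they are not). The widest array as a reason stays open: 0 genes passed without it, but the smallest adjusted p went from 0.183 to 0.110, genes at an unadjusted p under 0.05 from 337 to 407, and calls with random mouse effects from 99 to 167 genes (in simulation 24 of 182 clone calls of that fit on all arrays were false, a share that need not hold for the real calls). The mouse test may overstate its error: 2.04% of simulated unchanged clones had an unadjusted p under 0.05, and 3.74% of the real clones did. Real differences too small for this test stay open as well.

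The side of the ratio was put to a test through osmoprotective genes, which are known to rise when the medulla becomes more hypertonic. Only 5 of the 15 listed genes were measured. The list's camera adjusted p was 0.119, with 4 of 5 measured genes positive and Nfat5 negative, so the test did not decide which dye is the numerator. The list passed on the positive side without water-restricted mouse 3 (0.0488) and on arrays with the water-restricted mouse in Alexa Fluor 647 (0.0232), while with it in Alexa Fluor 546 the test pointed to the negative side (0.982).

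The 6 mice can be split in 10 ways, too few for a share under 0.05. For clones past the threshold all 10 splits gave at least the real 0, with 0 as the highest other, and the same 10 and 0 hold for genes. For gene lists 2 splits gave as many as the real 7, the highest other being 8, for water-restricted mice 1 and 3 with control mouse 1. For genes at an unadjusted p under 0.05, 4 splits gave as many as the real 337, the highest other being 820, for water-restricted mice 1 and 3 with control mouse 2. Without the widest array that split gave 642, and the highest other was 1307, for water-restricted mice 1 and 2 with control mouse 1, against a real 407, while for gene lists the real split gave 9 and the highest other 7. The split of water-restricted mice 1 and 2 with control mouse 1 also had 2 genes past the threshold, against a real 0. For genes, a split other than the groups thus gave several times the real count without that array. Every array compares a water-restricted with a control mouse, so array noise enters the real split and the others differently. The counts of the splits therefore cannot show whether the samples have another structure.

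Single arrays lay far from the other 5 of their dye orientation in 11 of 130 comparisons. The rule's bound is meant for about 1 in 20 with independent normal values, a rate that was not checked on these data. The SD of the array of water-restricted mouse 2 against control mouse 2 was 1.21 against 0.515 to 0.764. With the water-restricted mouse in Alexa Fluor 647, Wnt4 had -1.98 in mouse 1 against control 2 (others -1.48 to -1.21), Blnk -0.47 in mouse 3 against control 1 (others -1.12 to -0.92), and Hsph1 0.17 in mouse 3 against control 2 (others 0.69 to 0.89). Miox had 2.32 (others 0.71 to 1.19) and Aldoa 0.76 (others -0.16 to 0.16) in mouse 3 against control 1. Avpr1a had -1.78 in mouse 1 against control 3 (others -0.48 to 0.27) and Slc14a1 -1.08 in mouse 2 against control 1 (others -0.63 to -0.48). With it in Alexa Fluor 546, Pgk1 had 0.75 in mouse 3 against control 2 (others 0.33 to 0.48), while Ndufb9 had 1.13 (others 0.58 to 0.76) and Prkaca 0.64 (others -0.15 to 0.04) in mouse 2 against control 2.

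The dye orientations differed, by limma's test of the dye term, for 11 named genes. The term was -0.77 for Hsd3b1, -0.31 for Slc38a2 and -0.32 for Gatm. It was 0.28 for Bag3, 0.52 for Krt18, 0.64 for Slc22a7, 0.40 for Atf4, 0.61 for Ndufv1, 0.52 for Rpl21, 0.37 for Rps26 and 0.33 for Slc14a1.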

How the results depend on the processing

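Results without the array of water-restricted mouse 2 against control mouse 2, with random mouse effects and with fry in either direction were chosen after seeing the data, and the causes of the changes below were not tested unless stated. The counts of 0 clones and 0 genes held under median centring, scale normalization, equal weights, robust eBayes and an adjusted p under 0.1. They were also 0 without any 1 mouse (range 0 to 0), where 3 against 2 mice leave little chance of a call, so this says nothing of stability. Arrays as replicates gave 674 clones and 451 genes. This fit ignores that arrays share mice. In simulation 107 of its 285 clone calls were false, a share that need not hold for the real calls. Random mouse effects gave 219 clones and 99 genes, and 236 and 167 also without the array of water-restricted mouse 2 against control mouse 2. An unadjusted p under 0.05 gave 584 clones and 337 genes. Arrays with the water-restricted mouse in Alexa Fluor 647 gave 1 clone, of Pdxdc1, and 1 gene, and the 3 dye-swapped pairs 1 gene. Fits on 1 orientation have no dye term, so a dye effect enters their differences. The Pdxdc1 clone had -5.61 in that fit, against -0.32 on all arrays with a dye term of 5.43, so that call reflects the dye. Lists past camera numbered 7, with 5 to 9 under other settings of the values, and 0 with an estimated correlation and 0 with fry for change to 1 side (3 in either direction). Cholesterol synthesis passed camera under the block on the mouse number (adjusted p = 0.0491). Clones differing between mice, 28, became 10 with no dye term, 175 without the array of water-restricted mouse 2 against control mouse 2, and 0 to 0 without any 1 mouse, where fewer residual degrees of freedom remain. The dye effect, 527 clones, became 1 with the 6 arrays of the swapped pairs, which are fewer, and 903 without the array of water-restricted mouse 2 against control mouse 2. Signs reversed on arrays with the water-restricted mouse in Alexa Fluor 546 for Rpl21 (0.13), Rps26 (0.041), Slc14a1 (0.017) and Prkaca (0.057), and in Alexa Fluor 647 for Ndufv1 (-0.14). Leaving out 1 mouse, Adcy3 ran from -0.27 to 0.011, positive without water-restricted mouse 1, and Prkaca from -0.18 to 0.045, positive without water-restricted mouse 3, control mouse 1 or control mouse 3. The mouse number as a block gave 0 clones, 0 genes and 8 lists. Across clones, the deviations of same-numbered mice from their group means correlated at r = -0.009, -0.483 and -0.148. Differently numbered mice gave r from -0.483 to 0.507. These levels were fitted to shared arrays, so the values cannot decide whether the numbers pair the mice. The filter on complete clones, and for the comparison of groups the dye term, moved nothing and say nothing of stability.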

Other observations

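The genes and lists of this part were chosen after their values were seen. Under random mouse effects 64 of the 99 genes that passed were positive and 35 negative, and none passed in the comparison of mouse levels. Positive were Cxcl1, a neutrophil-attracting chemokine, at 1.53 (SE 0.26, adjusted p = 0.0110), Pdzk1, a scaffold protein of the proximal tubule brush border, at 1.20 (SE 0.20), and Nupr1, a stress-induced nuclear protein, at 1.03. Negative were Ccnd1, or cyclin D1, at -1.20 (SE 0.17, adjusted p = 0.00299), Hbb-b1, a beta-globin, at -1.02 (SE 0.16, adjusted p = 0.00514), Mt2, a metallothionein, at -0.90 and Sox4, a transcription factor, at -0.98. In simulation 24 of 182 clone calls of this fit were false, more than the threshold of 0.05 allows, a share that need not hold for the real calls.

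Of 28 lists set against the proximal tubule level of the mice, with 3 residual degrees of freedom, fatty acid oxidation had a slope of 0.41 (SE 0.12) and antioxidant genes of 0.29 (SE 0.05). With that level as a covariate the difference between groups went from 0.21 to -0.16 (SE 0.14) for fatty acid oxidation and from 0.24 to -0.02 (SE 0.06) for antioxidant genes. The antioxidant list includes Gpx3, plasma glutathione peroxidase, which had levels of 0.44 and 0.36 in water-restricted mice 1 and 2, a higher one in mouse 3, and 0.33, -1.10 and -1.53 in the control mice. H2-Eb1, a class II histocompatibility gene, ranged from -2.18 in control mouse 3 to 1.35 in water-restricted mouse 2 (limma F-test adjusted p = 0.0322).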
